A study of Mus musculus with 20 samples.

How the data were processed

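Messenger RNA was measured in 16 libraries of mouse embryos, each from 10 embryos, prepared with SMART-Seq v4 PLUS per the labels' protocols. The groups are siControl and siPcgf5 at the late 2-cell stage (2 and 2 libraries, 36 hours after insemination), siControl and siPcgf5 at the morula stage (2 and 2, 72 hours), and WT, Hetero KO and Homo KO at the 4-cell stage (2, 3 and 3, 48 hours). All libraries carry the same batch label. The series also holds 4 chromatin libraries against H2AK119ub1, which were not analysed here.

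Each deposited file holds RSEM gene values, with an expected count per gene that the authors did not normalise, per the file headers. The deposited TPM (transcript abundances scaled to a common total) were computed by RSEM over the genes of the annotation, per the file headers. STAR 2.7.10, RSEM 1.3.3, Bowtie2 2.4.5 and deepTools with mm10 are named in the submitters' processing notes, without their roles or order. Filters on reads are not stated. The files list 24411 genes by symbol, of which 23194 matched the RefSeq gene table of GRCm38.p6, used for positions and older names. No mitochondrially encoded gene is listed (0 of them), so no mitochondrial share could be read.

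Summed expected counts per library ran from 14310634 to 55620137. A gene at 0 in a whole group could stand at up to 3 counts over that group, and folds against such a group use this floor and are lower bounds. Floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

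Expected counts were rounded to whole numbers. The knockdown libraries (8) and the 4-cell libraries (8) were fitted apart, each with 1 coefficient per group and without a replicate block. Genes were kept by filterByExpr with a minimum count of 10, which left 16980 and 13766 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The groups of an experiment share the estimate of the spread, with common coefficients of variation of 0.460 and 0.517. The comparisons were siPcgf5 against siControl at each stage, the difference between those effects, Homo KO and Hetero KO against WT, Homo KO against Hetero KO, and siControl morula against siControl late 2-cell. CPM in the text use TMM-scaled library sizes, and list levels are means of log2 CPM with a prior count of 2.

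Gene lists were fixed before the data were examined, as were the comparisons, the naming rule and all alternatives but 1. They are 2-cell ZGA genes, the Obox family, oocyte and maternal genes, pluripotency, trophectoderm and primitive endoderm genes, PRC1 and PRC2 subunits, H2A deubiquitinases and partners, developmental Polycomb targets, imprinted genes, chromatin repressors with DNA methylation genes, p53 targets, ribosome biogenesis, cell cycle and replication, glycolysis, cumulus and granulosa markers, sperm markers, blood and immune markers, and ribosomal proteins by symbol pattern. Of 494 listed genes 488 matched the files, 1 by an older symbol. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted over the 20 lists of a comparison, and again with an estimated correlation. Neither setting decides alone whether a list changed, for reasons given with the stage comparison of the controls. Camera compares a list with the other genes. In comparisons of 2 groups, medians of the lists that passed were the same with genes at 0 in a group set to their bounds. For the difference between the knockdown effects no bounds were set. Stage lists hold genes with an adjusted p under 0.05 and a log2 fold change beyond 2 between siControl late 2-cell and siControl morula, tested at the 4-cell stage, or between siControl late 2-cell and WT 4-cell, tested at the morula.

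The naming rule took, per comparison, Pcgf5, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with groups that do not overlap and a mean of at least 10 CPM in the higher group, leaving out predicted genes and pseudogenes. Where fewer than 5 passed in a direction, it took the 5 with the smallest p in that direction, as values. It added the 4 members with the smallest p of each list past the threshold, and of the 2-cell ZGA, PRC1 and Polycomb target lists always, and the genes next to Pcgf5 at the 4-cell stage. The difference between the knockdown effects used no part of the rule on largest or smallest-p genes over all genes. Genes named outside the rule are said to be so. A gene that the rule took in Homo KO against WT is not reported here.

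The alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, the DESeq2 1.42.0 Wald test, limma with trend on log2(TPM + 1), only the groups compared, the replicate number as a block, leaving out each library in turn, and a log2 fold change beyond 1 for stage lists. With 1 library left out of a pair, the lone library is assumed to vary like the other groups. The ribosomal protein list without its S6 kinases and Rps19bp1 was added after the data were seen. For Hetero KO and Homo KO against the shared WT libraries, 20 sets of unchanged groups were simulated, over genes with a mean log2 CPM of at least 3. Each edgeR step was tested on simulated data, with counts drawn from the real genes' means and library sizes and 200 genes changed, 50 at each of 4 sizes. So many changed genes ease the adjusted threshold. The shares recovered therefore do not show what would be found where few genes change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.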

Results

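RNA was sequenced from 16 pools of mouse preimplantation embryos, 10 embryos per pool, in a knockdown and a knockout experiment. In the knockdown, small interfering RNA against Pcgf5 (siPcgf5) or control siRNA (siControl) was electroporated into embryos after in vitro fertilisation, and pools were collected at the late 2-cell stage, 36 hours after insemination, and at the morula stage, 72 hours after insemination. Each of these 4 groups held 2 libraries. In the knockout, embryos at the 4-cell stage, 48 hours after insemination, carried a heterozygous (Hetero KO) or homozygous (Homo KO) deletion of an MT2C_Mm repeat at Pcgf5, or none (WT). MT2C_Mm is a long terminal repeat of the retrovirus-like family to which MERVL belongs. There were 2 WT, 3 Hetero KO and 3 Homo KO libraries. The series title poses the question of how Pcgf5, driven by MERVL, bears on zygotic genome activation (ZGA), the onset of the embryo's own transcription.

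Depth in summed expected counts was 33757884 and 22435872 in siControl and 26053778 and 34631179 in siPcgf5 at the late 2-cell stage. At the morula it was 48876604 and 48572543 in siControl and 37628619 and 55620137 in siPcgf5. The 4-cell libraries held 14329188 and 17871206 counts in WT, 14310634, 17438598 and 15259769 in Hetero KO and 15395461, 15990703 and 15519707 in Homo KO. The 10 most abundant genes took between 5.27% and 8.45% of a library. Levels are given as CPM (counts scaled to a common library size), and changes as log2 fold changes with the standard error (SE) of the edgeR fit. P-values measure the spread between these libraries alone, since nothing states that replicates came from separate cultures. Reads shared among near-identical copies could be split between genes, so values for Zscan4, Usp17l, Tdpoz, Tcstv, Xlr, Obox, Hba-a1, Hba-a2 and the Gm4027, Gm8300 and Gm5662 genes are uncertain.

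Pcgf5 encodes a ring-finger subunit of a variant Polycomb repressive complex 1 (PRC1), which places ubiquitin on histone H2A. The gene lies on chromosome 19 at 36348329 to 36460970 of GRCm38.p6, the assembly of mm10. Both siPcgf5 late 2-cell libraries held less Pcgf5 mRNA than both controls, at 71.6 ± 25.6 CPM (SD, n = 2) against 558 ± 351 CPM (SD, n = 2). This left 12.8% of the control level, a log2 fold change of -2.96 (SE 0.443). At the morula stage the levels were 35.4 ± 4.77 CPM in siPcgf5 and 204 ± 55.2 CPM in siControl, so that 17.3% remained, with a log2 fold change of -2.53 (SE 0.436). Homo KO 4-cell embryos held 191 ± 25.0 CPM (SD, n = 3), 60.7% of the WT level of 314 ± 24.1 CPM (SD, n = 2). Whether the deletion removes a part of Pcgf5 that is counted here, which would lower the count by itself, could not be checked. The log2 fold change against WT was -0.72 (SE 0.185), and against Hetero KO it was -0.62 (SE 0.168), or 65% of the Hetero KO level. Hetero KO embryos held 293 ± 42.1 CPM (SD, n = 3), 93.3% of WT, with a log2 fold change of -0.10 (SE 0.186). All 3 Homo KO libraries lay below every WT and Hetero KO library.

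None of these Pcgf5 differences passed after adjustment over all genes with edgeR, where the adjusted p was 0.0790 at the late 2-cell stage, 0.242 at the morula, 0.237 for Homo KO against WT and 0.425 against Hetero KO. Adjusted over the 6 edgeR tests of Pcgf5 alone, the adjusted p was 0.000301, 0.000484, 0.00473 and 0.00505 in the same order, and 0.602 for Hetero KO against WT. DESeq2 called Pcgf5 lower in both knockdown comparisons and in Homo KO against WT. The late 2-cell controls differed from each other, at 310 and 806 CPM. Without siControl late 2-cell replicate 2 the log2 fold change of Pcgf5 was -2.14, and without siControl late 2-cell replicate 1 it was -3.45 and passed over all genes.

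**Figure D1:**
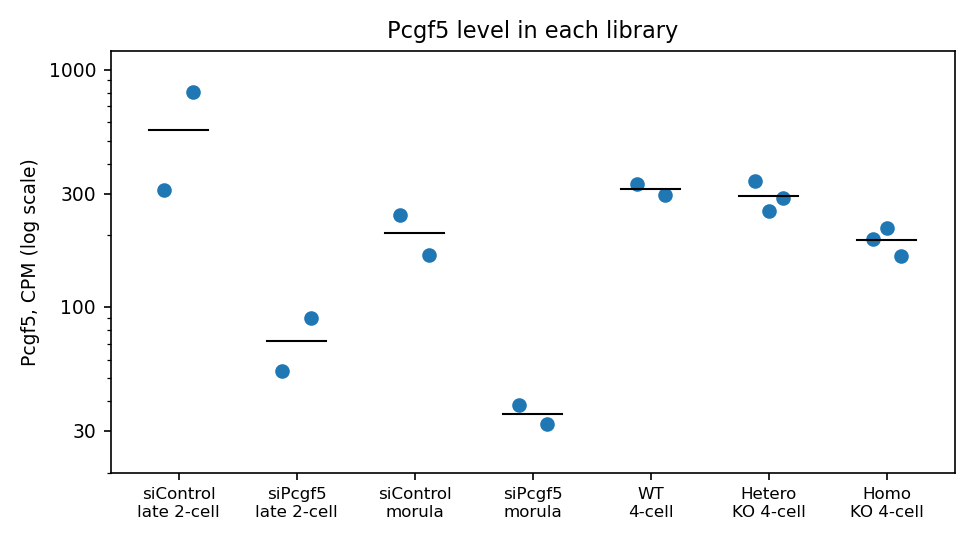
Pcgf5 level in each of the 16 libraries (points, CPM on a log axis) by group, with a line at each group mean. All siPcgf5 libraries lie below all siControl libraries of their stage, and the 3 Homo KO libraries (164 to 214 CPM) lie below the WT and Hetero KO libraries (255 to 338 CPM).

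The position of the deleted repeat is not given, so the genes next to Pcgf5 were read as well. Of 9 neighbours fixed in advance, Ankrd1 and Ppp1r3c had too few counts to be tested, and no other neighbour passed in any 4-cell comparison with edgeR. In Homo KO against WT, the log2 fold changes of the abundant neighbours were 0.36 (SE 0.266) for Rpp30, a subunit of ribonuclease P, -0.27 (SE 0.214) for Tnks2, a tankyrase, and 0.29 (SE 0.205) for Btaf1, a regulator of TATA-binding protein. Hectd2, the nearest protein-coding gene after Pcgf5, had a value of 1.87 (SE 0.751), and Cpeb3 a value of -1.46 (SE 0.526), at low levels of 2.02 to 29.2 CPM.

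The controls show what changed between the late 2-cell stage and the morula, and serve as the background for the other comparisons. Between these stages siControl embryos lost their 2-cell ZGA transcripts and their oocyte mRNAs, and gained ribosomal protein, pluripotency and p53 target mRNAs. Zscan4f, of a family that marks the late 2-cell stage, stood at 620 and 633 CPM and was listed at 0 in both morula libraries, at least 16300-fold lower. Zscan4c fell by 11.52 and Zscan4d by 10.10 on the log2 scale. Of the 10 named genes that rose most, Sycn, a zymogen granule protein, was at least 3160-fold higher, Serpinb9b, a serpin, at least 1620-fold and Msc, a transcription factor, at least 327-fold, each from 0 in both late 2-cell libraries. Phlda3, a p53 target, rose by 10.74 (SE 0.781), Gjb5, a gap junction protein, by 9.55 (SE 0.927) and Chmp4c by 9.13 (SE 0.518). Besides Zscan4f, the genes that fell most included Tctex1d1, at least 4510-fold lower, Scel, at least 2710-fold, Prl8a2, at least 2260-fold, and Cd36, a fatty acid transporter, at least 1770-fold. Floors are 3 counts over the group that stood at 0.

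By list, 32 of 37 tested 2-cell ZGA genes fell and 1 rose, and 39 of 42 oocyte and maternal genes fell, among them Omt2b (-9.38, SE 0.434), an oocyte protein, and Oog3 (-10.75, SE 0.579). Khdc3, a member of the subcortical maternal complex, was 1 of the 2 maternal genes that rose, by 5.94 (SE 0.306). Of 6 Obox homeobox genes 5 fell, such as Obox5 (-8.82, SE 0.610) and Obox2 (-7.33, SE 0.591). Genes of the ribosomal protein list rose in 86 of 94 cases and fell in 5, with Rpl26 up by 4.67 (SE 0.234) and Rpl8 by 4.20 (SE 0.228). By its symbol pattern the list takes in S6 kinases and Rps19bp1, and of its 83 other genes 82 rose and 1 fell. Pluripotency genes rose in 15 of 23 cases and fell in 2, among them Klf5 (3.70, SE 0.257), Tfcp2l1 (4.24, SE 0.307) and Tdgf1 (5.06, SE 0.443). Trophectoderm genes, of the outer cells that form placenta, rose in 13 of 24 cases and fell in 6, with Aqp3 (6.21, SE 0.411), a water channel, and Cldn4 (7.85, SE 0.732), a tight junction protein, among those that rose. Of 17 p53 targets 10 rose, such as Bax (2.94, SE 0.244) and Perp (6.38, SE 0.550), both tied to cell death, while Gadd45a fell (-4.33, SE 0.368). Ribosome biogenesis genes rose in 17 of 24 cases, among them Fbl (2.76, SE 0.252) and Ncl (1.95, SE 0.209), and cell cycle genes in 15 of 25, such as Mcm4 (2.23, SE 0.246), while Ccne2 fell (-2.50, SE 0.263).

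PRC1 genes went both ways, with 5 of 34 higher and 12 lower. Bmi1 fell by 5.23 (SE 0.243), Phc2 by 4.16 (SE 0.330) and Pcgf6 by 2.22 (SE 0.227), and Kdm2b rose by 1.93 (SE 0.257). Pcgf5 itself was lower in the morula, with a log2 fold change of -1.45 (SE 0.419) and an edgeR adjusted p of 0.0145. That call was lost without siControl late 2-cell replicate 2 (-0.67) and without siControl morula replicate 2 (-1.20). Of the developmental Polycomb targets 20 of 72 fell and 1 rose, Tbx20 (3.37, SE 0.307). Blood markers fell in 4 of 5 cases, with Hba-a2 down by 3.79 (SE 0.295), cumulus and granulosa markers in 5 of 8, and sperm markers in 3 of 5. PRC2 subunits had 3 higher and 3 lower of 12, H2A deubiquitinases and partners 1 higher and 7 lower of 12, imprinted genes 5 and 11 of 29, chromatin repressors 13 and 7 of 27, glycolysis genes 4 and 6 of 18 and primitive endoderm genes 5 and 2 of 13.

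In total, edgeR called 4220 genes higher and 4766 lower of 16980 tested, DESeq2 4053 and 5540, and limma on log2(TPM + 1) 2452 and 7388. These other scalings moved the median of all genes by -0.17 and -0.16 on the log2 scale, and their shares of higher calls were 42.2% and 24.9% against 47% with edgeR. Groups did not overlap in 13378 genes, 78.8% against 33.3% by chance. With camera, 10 lists passed, from an adjusted p of 6.59e-44 for ribosomal proteins to 0.0492 for trophectoderm genes. Medians were 3.08 for ribosomal proteins, 2.60 for pluripotency, 2.69 for p53 targets, 1.53 for trophectoderm, 1.03 for ribosome biogenesis, 1.17 for cell cycle, -4.14 for 2-cell ZGA, -6.32 for maternal, -8.07 for Obox and -4.03 for blood genes. No list passed with an estimated correlation, where camera's adjusted p ran from 0.187 to 0.417 for these 10 lists. These included ribosomal proteins, with 86 of 94 genes called higher, and 2-cell ZGA genes, with 32 of 37 called lower. The test thus missed lists whose genes mostly passed singly, and a call lost with it does not show an unchanged list. The preset correlation of 0.01 lies below the estimates for these lists, 0.49 and 0.23, and treats their genes as more independent than estimated. A call with the preset alone is therefore not firm either. The trophectoderm call was lost without siControl late 2-cell replicate 1 (1.45) or replicate 2 (1.27), and the blood call without siControl late 2-cell replicate 1 (-3.78). DESeq2 ended the trophectoderm call (1.36), and limma on log2(TPM + 1) ended the blood call and those of trophectoderm (0.32), ribosome biogenesis (0.09) and cell cycle genes (0.14). With limma the median was 1.3 for pluripotency genes and 1.14 for p53 targets, both still past the threshold. Without the same replicate 1, the ribosome biogenesis median was 0.64. The primitive endoderm and glycolysis lists, neither of which passed, had medians, means and tests that differed in sign.

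Knockdown at the late 2-cell stage addresses what happens to ZGA transcripts when Pcgf5 mRNA is removed. siPcgf5 embryos held more ribosomal protein mRNA than controls and somewhat more mRNA of the 2-cell ZGA genes, and less of the primitive endoderm genes, by a camera test that none of these lists passed with an estimated correlation. Of 94 genes in the ribosomal protein list, 88 had positive log2 fold changes, with a median of 0.35. Without its S6 kinases and Rps19bp1, 82 of 83 were positive. The 37 2-cell ZGA genes had a median of 0.23, and 27 of them were positive. Of 13 primitive endoderm genes, of the lineage that forms the yolk sac, 11 were negative, with a median of -0.57. siControl late 2-cell replicate 1 stood apart in several lists, and siControl replicate 2 lay closer to the siPcgf5 libraries. The summed CPM of 8 Y-linked genes was 61.7 in siControl replicate 1 and 232 in siControl replicate 2, against 160 and 154 in siPcgf5. Whether the sex makeup of these pools differs was not tested. In mean log2 CPM that replicate 1 had 5.99 for ZGA genes against 6.44 to 6.66 in the other 3 libraries, 6.30 for ribosomal proteins against 6.78 to 6.99, 2.69 for p53 targets against 3.21 to 3.31, 7.01 for maternal genes against 6.36 to 6.53 and 5.41 for blood markers against 3.47 to 4.24.

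No gene of these lists passed singly over all genes, and 0 passed when adjusted over the list alone. Rpl26 had a log2 fold change of 0.83 (SE 0.204), Rpl41 of 0.80 (SE 0.210), Rps29 of 0.63 (SE 0.206) and Rps27rt of 0.60 (SE 0.196). Among ZGA genes, Zscan4d had 0.82 (SE 0.381), Tcstv3 0.85 (SE 0.480), Usp17lc, a deubiquitinase of a multi-copy family, 0.84 (SE 0.356) and Zscan4c 0.65 (SE 0.398). Zscan4d stood at 493 and 508 CPM in siPcgf5 and 229 and 336 CPM in siControl. Among primitive endoderm genes, the transcription factor Gata6 had -0.71 (SE 0.235) and the receptor Pdgfra -1.38 (SE 0.569). PRC1 subunits had a median of -0.02, with Max at -0.66 (SE 0.277), Pcgf6 at -0.43 (SE 0.217) and Bmi1 at -0.37 (SE 0.203). Developmental Polycomb targets had a median of -0.28 over 72 genes. Hoxa2 was listed at 0 in both siPcgf5 libraries, at least 22.5-fold lower. Maternal genes had a median of -0.25, and pluripotency genes of 0.25, with Tbx3 at 1.31 (SE 0.276), the 1 pluripotency gene that passed adjusted over the list alone. Tbx3 was named after its values were seen.

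Over all genes, edgeR called 1 gene higher and 1 lower of 16980. These are Gm5891, a predicted gene at 24.3 and 18.0 CPM in siPcgf5 against 0.0449 and 0.112 CPM in siControl (log2 fold change 8.12, SE 0.702, edgeR adjusted p 0.0109), and Serpinb6c, a serpin at 0 in both siPcgf5 libraries against 1.24 and 0.821 CPM (edgeR adjusted p 0.0387). Both were named after their values were seen. The genes of the naming rule below that threshold were Malat1, an abundant nuclear RNA (-1.54, SE 0.208, edgeR adjusted p 0.0577), Pdcl3 (-1.49, SE 0.208), Marcks (-1.29, SE 0.288) and Cnot6l, a deadenylase that removes maternal mRNA (-1.17, SE 0.271). On the higher side they were Dnajb1, a heat shock co-chaperone (1.08, SE 0.205), Frrs1 (1.15, SE 0.270) and Mylpf (1.01, SE 0.235). None of these was called.

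By camera, ribosomal proteins (adjusted p = 1.65e-14), primitive endoderm genes (adjusted p = 0.00847) and 2-cell ZGA genes (adjusted p = 0.0115) passed. None did with an estimated correlation, with an adjusted p = 0.853 for ribosomal proteins and ZGA genes and an adjusted p = 0.484 for primitive endoderm genes. The ZGA call was lost without siControl late 2-cell replicate 1 (median 0.16) and without siPcgf5 late 2-cell replicate 2 (0.18), and the median was 0.59 without siControl late 2-cell replicate 2. The primitive endoderm call was lost without siControl late 2-cell replicate 2 (-0.54), without siPcgf5 late 2-cell replicate 1 (-0.49) and with limma on log2(TPM + 1) (-0.22). Its median was -0.30 without siControl late 2-cell replicate 1 and -0.98 without siPcgf5 late 2-cell replicate 2. The ribosomal protein median ran from 0.12 without siControl late 2-cell replicate 1 to 0.68 without siControl late 2-cell replicate 2. The gene counts were 0 higher and 0 lower without either siPcgf5 library, 2 and 3 without siControl replicate 1, and 5 and 8 without siControl replicate 2. DESeq2 called 27 higher and 45 lower, and limma 8 and 6. At an unadjusted p under 0.05, 947 genes lay below the threshold, 5.6% against 5% by chance, and groups did not overlap in 5303 genes, 31.2% against 33.3% by chance. In simulated data of this comparison, edgeR recovered 24% of genes changed by a log2 fold change of 1, 88% at 2, 96% at 3 and 100% at 4, with 11 false calls. Trophectoderm, imprinted, glycolysis and blood lists, none of which passed, had medians, means and tests that differed in sign.

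At the morula stage, no gene and no list passed in siPcgf5 against siControl with edgeR or camera. This comparison asks what a lasting loss of Pcgf5 mRNA does after ZGA. The gene with the smallest adjusted p was Dcc, a netrin receptor, at 3.25 and 2.51 CPM in siPcgf5 against 16.5 and 14.2 CPM in siControl (log2 fold change -2.42, SE 0.312, edgeR adjusted p 0.0992). Other low values were those of Xlr3c (-2.98, SE 0.593), an X-linked gene of a multi-copy family, Mospd2 (-1.81, SE 0.376) and Slc25a31, a mitochondrial ADP/ATP carrier (-1.26, SE 0.265). Without siControl morula replicate 2 the values were -1.46 for Xlr3c and -1.11 for Mospd2. On the higher side were Ctsb, a lysosomal protease (0.88, SE 0.223), Tmem37 (0.87, SE 0.219), Atp6ap1l (1.04, SE 0.319), Tubb5, a tubulin (0.78, SE 0.249), and Yy2 (0.72, SE 0.230).

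Of 37 2-cell ZGA genes, 23 had negative values, with a median of -0.09 and a camera adjusted p = 0.143. Their mean level was 0.39 log2 CPM in siPcgf5 morula replicate 2, against 1.54 in siPcgf5 morula replicate 1 and 1.41 and 1.54 in siControl. They were near their lowest levels at this stage. Usp17ld, at 0.258 and 0.203 CPM against 0.920 and 1.04 CPM, passed adjusted over the list alone (-2.09, SE 0.468) and not over all genes. Gm5662 had -1.66 (SE 0.579) and Spz1 -1.78 (SE 0.665). PRC1 subunits had a median of 0.02, with Mga at -0.46 (SE 0.252), Phc2 at 0.52 (SE 0.304), Pcgf1 at 0.48 (SE 0.309) and Pcgf3 at 0.41 (SE 0.279). Developmental Polycomb targets had a median of -0.19, or -0.31 with the 17 genes that stood at 0 in a group set to their bounds. Median values were -0.33 for p53 targets, of which 14 of 17 were negative, 0.15 for cell cycle genes, 0.10 for pluripotency genes and -0.08 for ribosomal proteins. Of the blood markers Hba-a1 and Hba-a2 passed adjusted over the list alone, and not over all genes. Both were named after their values were seen, and Hba-a2 had a value of 0.75. The 8 cumulus and granulosa markers had a median of 0.98, or 0.47 with 3 genes at their bounds.

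The edgeR fit called 0 of 16980 genes, with 716 at an unadjusted p under 0.05, 4.2% against 5% by chance. DESeq2 called 5 genes higher, which are Ccdc69, Fbxw14, Ppp1r3c, Slc10a4 and Tex16, named after their values were seen, and 18 lower. Limma called 0 in either direction. Without siControl morula replicate 1, edgeR called 2 genes lower, and without siPcgf5 morula replicate 1 it called 4. Groups did not overlap in 5349 genes, 31.5% against 33.3% by chance. Recovery in simulated data of this comparison was 22% at a log2 fold change of 1, 88% at 2, 100% at 3 and 98% at 4, with 8 false calls. Pcgf5, at -2.53 in the real data, did not pass over all genes. The PRC1, PRC2, H2A deubiquitinase, glycolysis and sperm lists had medians, means and tests that differed in sign.

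The difference between the knockdown effects, morula minus late 2-cell, tests whether siPcgf5 acted differently at the stages. Ribosomal protein genes, 2-cell ZGA genes and p53 targets had a lower knockdown effect in the morula than at the late 2-cell stage, though not with an estimated correlation in the camera test. The median difference for ribosomal proteins was -0.44, negative in 88 of 94 genes, with Rpl26 at -1.08 (SE 0.285), Rpl41 at -0.81 (SE 0.296) and Rps29 at -0.79 (SE 0.290). For the 2-cell ZGA list the median was -0.51, negative in 25 of 37 genes, with Usp17ld at -2.07 (SE 0.599), Usp17lc at -1.57 (SE 0.546), Tdpoz1 at -1.03 (SE 0.445) and Arg2 at -1.17 (SE 0.521). For p53 targets it was -0.43, negative in 12 of 17 genes, with Cdkn1a, an inhibitor of the cell cycle, at -0.72 (SE 0.362), Pmaip1, which promotes cell death, at -1.48 (SE 0.675), and Eda2r at -1.04 (SE 0.498). No list gene passed singly, over all genes or adjusted over the list alone. The difference for Pcgf5 was 0.43 (SE 0.583). Among PRC1 genes, Pcgf6 had 0.75 (SE 0.308) and Bmi1 0.50 (SE 0.288), and the Polycomb target Pax6 had 1.67 (SE 0.655). The camera adjusted p = 4.27e-10 for ribosomal proteins, 0.0111 for ZGA genes and 0.0336 for p53 targets. The adjusted p = 0.674 with an estimated correlation for each of these lists.

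The ZGA call for this difference was lost without siControl late 2-cell replicate 1 (-0.54), siPcgf5 late 2-cell replicate 2 (-0.51) or siPcgf5 morula replicate 2 (-0.39). Its median was -0.93 without siControl late 2-cell replicate 2, -0.18 without siControl morula replicate 1 and -0.94 without siPcgf5 morula replicate 1. The p53 call was lost without siControl late 2-cell replicate 1 (-0.33), siPcgf5 late 2-cell replicate 1 (-0.34) or replicate 2 (-0.37), siControl morula replicate 2 (-0.25) or siPcgf5 morula replicate 1 (-0.37). The ribosomal protein median was -0.18 without siControl late 2-cell replicate 1 and -0.70 without siControl late 2-cell replicate 2. The edgeR fit called 0 genes, with 842 at an unadjusted p under 0.05, 5% as by chance. DESeq2 called 18 higher and 14 lower, and limma called 0 higher and 1 lower, with the median of all genes moved by 0.12. Without siPcgf5 morula replicate 1, edgeR called 1 gene lower. In simulated data of this contrast, 6% of genes were recovered at a log2 difference of 1, 60% at 2, 96% at 3 and 98% at 4, with 21 false calls. The trophectoderm, H2A deubiquitinase, Polycomb target and cell cycle lists had medians, means and tests that differed in sign.

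**Figure D2:**
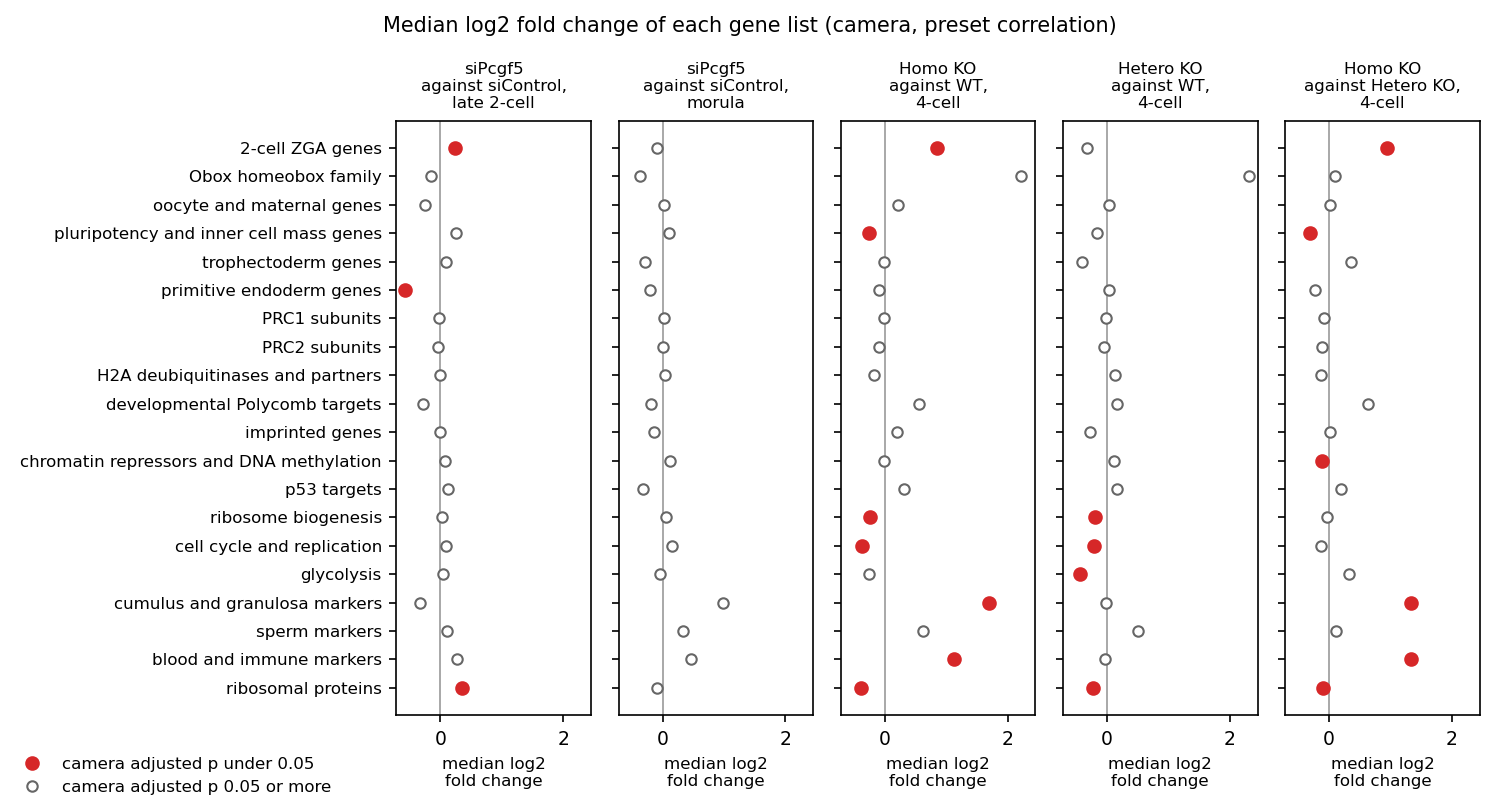
Median log2 fold change of each of the 20 gene lists (points) in the knockdown and knockout comparisons. Filled red points mark a camera adjusted p under 0.05 with the preset correlation and open points mark other lists. 2-cell ZGA genes lie at 0.94 in Homo KO against Hetero KO and at -0.09 in the morula knockdown.

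Homo KO against WT asks what the loss of the repeat on both chromosomes does at the 4-cell stage. Homo KO embryos held more mRNA of the 2-cell ZGA genes than WT, and less of the ribosomal protein, cell cycle, pluripotency and ribosome biogenesis genes, by a camera test with a preset correlation. None of these lists passed with an estimated correlation, and WT replicate 1 lay above 2 of the 3 Homo KO libraries in the ZGA genes. The 37 ZGA genes had a median log2 fold change of 0.85, with 29 positive. Of 92 genes in the ribosomal protein list 76 were negative, with a median of -0.38. Of 25 cell cycle genes 21 were negative, with a median of -0.37. Cumulus and granulosa markers, of the cells that surround the oocyte, were higher in Homo KO with a median of 1.69, and blood and immune markers with a median of 1.12. Each was positive in all 5 genes tested, of 15 and 10 listed, the others having too few counts. These 2 calls too were lost with an estimated correlation. In siControl embryos these markers also fell from the late 2-cell stage to the morula, in 5 of 8 and 4 of 5 genes tested there.

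Replicate libraries differed in the ZGA genes. Their mean level on the log2 CPM scale was 4.67 in WT replicate 1 and 2.33 in WT replicate 2, against 4.60, 4.56 and 4.80 in Homo KO. Without WT replicate 2 the ZGA call was lost (median 0.14), without WT replicate 1 the median was 2.52, and without Homo KO replicate 3 it was 0.53. Spz1, a transcription factor first found in testis, stood at 37.7, 36.0 and 33.6 CPM in Homo KO and 19.1 and 17.3 CPM in WT (0.98, SE 0.267). Gm4027 had 2.26 (SE 1.04), with 4.00 without WT replicate 1 and 1.47 without WT replicate 2, and D5Ertd577e had -0.84 (SE 0.283). Usp17le was listed at 0 in both WT libraries, at least 5.85-fold higher by a floor that covers counting error only. It did not reach an unadjusted p under 0.05, where Spz1 was the 1 ZGA gene on the higher side. The Obox family, with a median of 2.21 and 5 of 6 genes positive, did not pass (camera adjusted p = 0.0605). Homo KO replicate 3 stood apart here, at a mean level of 8.54 log2 CPM against 6.21 and 6.57 in the other Homo KO libraries and 6.06 and 5.05 in WT.

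Lower values among ribosomal proteins included Rps2 (-1.08, SE 0.201), Rpl37a (-0.70, SE 0.183) and Rps12 (-0.68, SE 0.201). The list also takes in S6 kinases by its symbol pattern, and of these Rps6ka3, a signalling kinase, had 1.79 (SE 0.392). Rps2 and Rps6ka3 passed adjusted over the list alone, and not over all genes. Of the cell cycle genes, Rrm2 (-1.04, SE 0.209), a subunit of ribonucleotide reductase, Cdc6 (-0.90, SE 0.239) and Cdt1 (-0.87, SE 0.247), which load the replicative helicase, and the mitotic kinase Aurka (-0.65, SE 0.184) passed adjusted over the list alone, and 0 over all genes. Of 23 pluripotency genes 17 were negative, with a median of -0.25. Tet1, which oxidises 5-methylcytosine, had -0.68 (SE 0.195), Klf17 -0.79 (SE 0.272), Klf2 -1.05 (SE 0.408) and Esrrb -1.51 (SE 0.516). Of 24 ribosome biogenesis genes 19 were negative, with a median of -0.24. Fbl, which methylates ribosomal RNA, had -0.83 (SE 0.246), Nop56 -0.57 (SE 0.184), Polr1a, of RNA polymerase I, -0.88 (SE 0.319) and Nop16 0.57 (SE 0.197). In the same libraries the cumulus and blood markers were higher, with Tnfaip6 at 2.48 (SE 0.878), Serpine2 at 0.93 (SE 0.359), Vim at 2.01 (SE 0.967), Lyz2 at 3.53 (SE 1.24), Hba-a2 at 1.12 (SE 0.434) and Cd74 at 0.39 (SE 0.782).

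PRC1 subunits had a median of -0.01, with Skp1a at 0.64 (SE 0.206), Bmi1 at 0.78 (SE 0.344), Pcgf1 at -0.46 (SE 0.189) and Phc1 at -1.13 (SE 0.534). Developmental Polycomb targets, tested in 39 genes, had a median of 0.55 and did not pass (camera adjusted p = 0.419). Hoxb2 was listed at 0 in both WT libraries, at least 6.78-fold higher. Among genes of the naming rule, those that rose with the smallest p were the X-linked Xlr4c (1.40, SE 0.230) and Xlr4a (1.64, SE 0.282), the cytochrome P450 gene Cyp2c67 (3.56, SE 0.613), Zfp781 (1.18, SE 0.206) and Ak6 (0.85, SE 0.151). Cyp2c67 had 4.80 without WT replicate 1 and 2.87 without WT replicate 2. Genes that fell with small p included Hand1, a transcription factor of trophoblast cells (-1.88, SE 0.265), Rps2, the ribosomal RNA precursor Rn45s (-1.20, SE 0.226) and Scamp4 (-2.52, SE 0.482). None passed over all genes, with an edgeR adjusted p of 0.174 for Hand1 and 0.202 for the others. Hand1 passed adjusted over the trophectoderm list alone, whose median was -0.01 and mean 0.20.

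By camera the adjusted p = 6.85e-08 for ribosomal proteins, 0.000603 for cell cycle, 0.00168 for ZGA, 0.0143 for cumulus, 0.0222 for pluripotency and 0.0247 for blood and for ribosome biogenesis genes. For each of these 7 lists the adjusted p = 0.703 with an estimated correlation. The cumulus call was lost without WT replicate 2 (1.52) and Homo KO replicate 3 (1.07), with 2.68 without WT replicate 1, and with no filter on low counts (1.45). The blood call was lost without WT replicate 2 (0.69), Homo KO replicate 1 (1.23) and Homo KO replicate 2 (0.86), with 1.90 without WT replicate 1. The pluripotency call was lost without WT replicate 2 (-0.14) and Homo KO replicate 2 (-0.38), with -0.66 without WT replicate 1 and -0.54 without Homo KO replicate 3. The ribosome biogenesis call was lost without WT replicate 2 (-0.23), Homo KO replicate 2 (-0.19) and Homo KO replicate 3 (-0.18), and the ribosomal protein median was -0.17 without WT replicate 2. DESeq2 ended the ZGA call, with a median of 0.89, and the blood call, with 1.14.

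Here edgeR called 0 of 13766 genes, with 921 higher and 780 lower at an unadjusted p under 0.05, 12.4% against 5% by chance. Genes higher in siControl at the late 2-cell stage than at the morula, 2774 of those tested, held 323 of the 921 and 28 of the 780. Genes lower there, 2074 of those tested, held 32 and 307. Genes move together, so the shares given as by chance in this paragraph do not test an excess. DESeq2 called 234 higher and 94 lower, and limma 0. Without WT replicate 1, edgeR called 26 genes higher. Groups did not overlap in 4184 genes, 30.4% against 20% by chance. Simulated data of this comparison gave recovery of 14% at a log2 fold change of 1, 72% at 2, 94% at 3 and 98% at 4, with 7 false calls. The primitive endoderm and H2A deubiquitinase lists, like the trophectoderm list, had medians, means and tests that differed in sign.

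**Figure D3:**
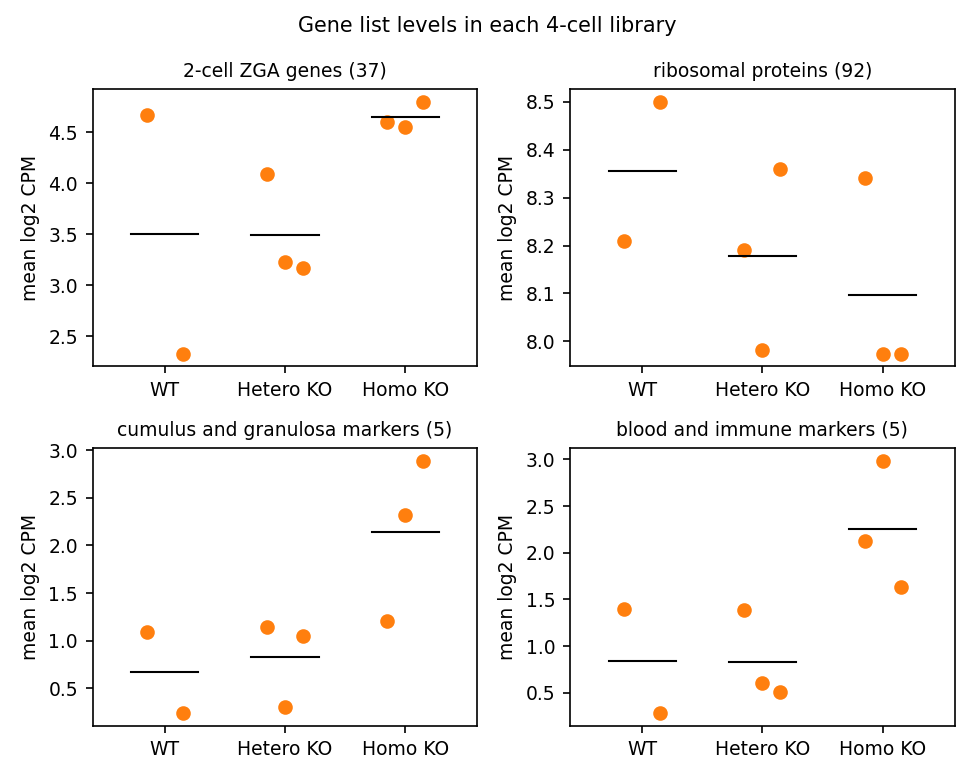
Mean log2 CPM of 4 gene lists in each 4-cell library (points), with a line at each group mean. The 2-cell ZGA genes lie at 4.67 and 2.33 in WT, 3.16 to 4.09 in Hetero KO and 4.56 to 4.80 in Homo KO, and the cumulus and blood markers are highest in Homo KO libraries.

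Hetero KO against WT asks what the loss of 1 copy of the repeat does. Hetero KO embryos held less mRNA of the ribosomal protein, glycolysis, cell cycle and ribosome biogenesis genes than WT by camera, though no list passed with an estimated correlation. Of 92 genes in the ribosomal protein list 81 were negative, with a median of -0.23. Of 18 glycolysis genes 16 were negative, with a median of -0.44. The 25 cell cycle genes had a median of -0.21, with 18 negative, and the 24 ribosome biogenesis genes a median of -0.19, with 16 negative. The 2-cell ZGA list did not pass, with a median of -0.33 (camera adjusted p = 0.768). Cumulus and blood markers had medians of -0.01 and -0.04 and did not pass either.

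Named members of these lists were Rps2 (-0.58, SE 0.202) and Rps12 (-0.50, SE 0.201), Fbl (-0.81, SE 0.246) and Nop56 (-0.50, SE 0.184), Cdt1 (-0.64, SE 0.247) and Mcm7 (-0.84, SE 0.360), and the glycolytic enzymes Ldha (-1.14, SE 0.356), Pkm (-0.86, SE 0.322) and Hk2 (-1.07, SE 0.527). Pkm had -0.26 without WT replicate 1. No list gene passed over all genes, and 0 passed adjusted over the list alone. Of the ZGA genes, Zscan4d had -1.17 (SE 0.662), Usp17lc -2.13 (SE 1.21) and D5Ertd577e -0.70 (SE 0.284). The first turned to 0.77 and Usp17lc to 2.90 without WT replicate 1, in which Usp17lc stood at 35.2 CPM against 0.535 CPM in WT replicate 2. PRC1 subunits had a median of -0.02, with Cbx2 at 1.72 (SE 0.719) and L3mbtl2 at -0.83 (SE 0.379), and developmental Polycomb targets 0.16. The naming rule gave Mynn (0.92, SE 0.191), Rgs9bp (2.49, SE 0.540), the RNA export factor Nxf2 (1.03, SE 0.235), Btbd10 (1.13, SE 0.265) and Fam122b (0.99, SE 0.233) on the higher side. On the lower side were Elovl6, a fatty acid elongase (-1.19, SE 0.226), Rn45s (-1.02, SE 0.226), Uba1y (-1.90, SE 0.461), R3hcc1 (-1.51, SE 0.368) and Ankrd13a (-1.19, SE 0.305). None of these passed, each with an edgeR adjusted p of 0.945. Uba1y is Y-linked, and Nxf2 and Fam122b are X-linked. The summed CPM of 8 Y-linked genes was 71.7, 138 and 51.8 in Hetero KO against 118 and 152 in WT. Xist stood at 19.7, 40.2 and 103 CPM against 11.7 and 64.2 CPM. The sex makeup of these pools may differ, which was not tested.

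By camera the adjusted p = 9.15e-06 for ribosomal proteins, 0.00137 for glycolysis, 0.00835 for cell cycle and 0.00885 for ribosome biogenesis. With an estimated correlation the adjusted p = 0.903 for ribosomal proteins and 0.780 for the other 3 lists. The ribosomal protein call was lost without WT replicate 2 (-0.05) and Hetero KO replicate 2 (-0.09), with -0.36 without WT replicate 1. The glycolysis call was lost without WT replicate 1 (-0.05), with -0.68 without WT replicate 2. The cell cycle call was lost without WT replicate 2 (-0.12) and Hetero KO replicate 2 (-0.26). The ribosome biogenesis call was lost without WT replicate 2 (-0.16), Hetero KO replicate 1 (-0.16) and Hetero KO replicate 2 (-0.14), with -0.30 without Hetero KO replicate 3. The count of genes called was 0 of 13766 with edgeR, 6 higher and 1 lower with DESeq2 and 0 with limma. At an unadjusted p under 0.05 there were 656 genes, 4.8% against 5% by chance, and groups did not overlap in 2833 genes, 20.6% against 20% by chance. Recovery in simulated data of this comparison was 22% at a log2 fold change of 1, 86% at 2, 96% at 3 and 100% at 4, with 14 false calls. The primitive endoderm, PRC1, PRC2, Polycomb target and cumulus lists had medians, means and tests that differed in sign.

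Homo KO against Hetero KO compares the deletion on both chromosomes with that on 1, with 3 libraries each. The 2-cell ZGA genes were higher in Homo KO, with 29 of 37 positive, a median of 0.94 and a mean of 1.10, a camera call that, like those of the lists below, was lost with an estimated correlation. All 3 Homo KO libraries (4.60, 4.56 and 4.80 mean log2 CPM) lay above all 3 Hetero KO libraries (4.09, 3.23 and 3.16). Cumulus markers (median 1.34) and blood markers (median 1.33) were higher too, in all 5 genes tested of each, from 15 and 10 listed. With limma the cumulus median was 0.76. Pluripotency genes were lower, with 19 of 23 negative and a median of -0.32, as were chromatin repressors (20 of 27 negative, median -0.12) and ribosomal proteins (74 of 92 negative, median -0.10).

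The ZGA list had 9 genes higher at an unadjusted p under 0.05 and 0 lower, with 0 called over all genes and 0 adjusted over the list alone. Gm8300 stood at 297, 275 and 324 CPM in Homo KO against 81.9, 13.3 and 42.6 CPM in Hetero KO. Usp17lc stood at 47.3, 37.0 and 25.8 CPM against 6.5, 3.47 and 2.27 CPM (3.17, SE 1.18). Gm4027 had 2.59 (SE 0.901) and Spz1 0.77 (SE 0.233). Of the cumulus markers, Tnfaip6 (3.06, SE 0.774), a hyaluronan-binding protein, and Serpine2 (1.08, SE 0.315), a protease inhibitor, passed adjusted over the list alone, and 0 over all genes. Tnfaip6 had 2.24 without Homo KO replicate 3. Of the blood markers, the globin gene Hba-a2 had 1.16 (SE 0.379), the lysozyme Lyz2 2.57 (SE 0.995) and Cd74 1.33 (SE 0.709). Tet1 had -0.43 (SE 0.176), Nr5a2 -0.55 (SE 0.247), Klf2 -0.81 (SE 0.373) and Esrrb -0.99 (SE 0.474). Among chromatin repressors, the histone chaperone partner Atrx had -0.60 (SE 0.192), Kdm6a, an X-linked H3K27 demethylase, -0.74 (SE 0.258), Morc3 -0.46 (SE 0.185) and Ehmt2, an H3K9 methyltransferase, -0.82 (SE 0.343). Atrx is X-linked like Kdm6a, and the markers of sex differed between these libraries. The summed CPM of 8 Y-linked genes was 106, 264 and 202 in Homo KO against 71.7, 138 and 51.8 in Hetero KO, and Xist stood at 40.5, 6.11 and 5.64 CPM against 19.7, 40.2 and 103 CPM, so the sex makeup of the pools may differ. Xist was named after its values were seen. Rps2 had -0.50 (SE 0.183), Rps4x -0.65 (SE 0.276) and Rps27 1.12 (SE 0.378). PRC1 subunits had a median of -0.09, with Skp1a at 0.45 (SE 0.181) and Auts2 at 0.81 (SE 0.335), and Polycomb targets a median of 0.64 (camera adjusted p = 0.191).

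The naming rule gave, on the higher side, the small nucleolar RNA host gene Snhg3 (1.36, SE 0.222), the hormone gene Sct (2.17, SE 0.411), Gt(ROSA)26Sor (1.56, SE 0.306), Ndufa4 (0.92, SE 0.182) and Robo1 (2.85, SE 0.568). On the lower side were Hand1 (-1.38, SE 0.244), Msl3 (-1.02, SE 0.225), Nxf2 (-0.92, SE 0.205), Hmox1, a haem oxygenase (-1.66, SE 0.371), and Szrd1 (-1.03, SE 0.232). None passed, with an edgeR adjusted p of 0.406 for each. Of these, Nxf2 is X-linked like Atrx and Kdm6a, so the difference in the markers of sex given above bears on it too. Hand1 passed adjusted over the trophectoderm list alone. So did Rian, a maternally expressed imprinted RNA, over the imprinted list alone, at 1.68, 3.91 and 9.30 CPM in Homo KO against 0.201, 0 and 0.0689 CPM in Hetero KO, with 3.12 and 0.713 CPM in WT. Rian was named after its values were seen.

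By camera the adjusted p = 6.75e-07 for the ZGA list, 0.00243 for cumulus and for blood markers, 0.0180 for pluripotency genes and 0.0344 for chromatin repressors and for ribosomal proteins. With an estimated correlation the adjusted p = 0.437 for ZGA genes, 0.331 for cumulus, blood and chromatin repressors, 0.760 for pluripotency and 0.884 for ribosomal proteins. The ZGA call was kept without each library in turn, with medians from 1.01 to 1.62, the highest without Hetero KO replicate 1. The pluripotency call was lost without Hetero KO replicate 3 (-0.17) and Homo KO replicate 2 (-0.33). The chromatin repressor call was lost without Hetero KO replicate 2 (-0.17), Hetero KO replicate 3 (-0.20), Homo KO replicate 2 (-0.17) and Homo KO replicate 3 (-0.25). The ribosomal protein call was lost without Hetero KO replicate 3 (-0.0012), Homo KO replicate 2 (-0.05) and Homo KO replicate 3 (-0.04). Its median was -0.22 without Hetero KO replicate 2 and -0.23 without Homo KO replicate 1. With edgeR 0 of 13766 genes were called, and 702 were higher and 430 lower at an unadjusted p under 0.05, 8.2% against 5% by chance. Since genes move together, the shares given as by chance in this paragraph do not test an excess. DESeq2 called 89 higher and 22 lower, and limma 2 higher and 0 lower. Without Homo KO replicate 1, edgeR called 3 higher and 1 lower. Groups did not overlap in 2025 genes, 14.7% against 10% by chance. In simulated data of this comparison, 28% of genes were recovered at a log2 fold change of 1, 88% at 2, 100% at 3 and 100% at 4, with 11 false calls. The maternal and H2A deubiquitinase lists had medians, means and tests that differed in sign.

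Genes that fall or rise as control embryos pass from the late 2-cell stage to the morula were then read at the 4-cell stage, from libraries that take no part in defining them. The list of genes higher at the late 2-cell stage held 2774 tested genes, and the list of genes lower there 2074. In Homo KO against WT the median log2 fold change of these lists was 0.55 and -0.37, with 2039 and 517 positive genes. DESeq2 called 234 genes higher in Homo KO than in WT, and 83 of these are in the late 2-cell list, and 42 of the 94 it called lower are in the other list. Of all 13766 tested genes, 2774 and 2074 are in these lists. Their members move together, with estimated correlations of 0.16 and 0.18, so these counts are not of independent genes. In Hetero KO against WT the medians were 0.30 and -0.18, and in Homo KO against Hetero KO 0.15 and -0.17. The camera adjusted p = 1.23e-10 and 8.4e-13 for Homo KO against WT, 1.35e-06 for both lists in Hetero KO against WT, and 0.000844 and 3.01e-05 in Homo KO against Hetero KO. With an estimated correlation the adjusted p = 0.160, 0.286 and 0.436 in the same order. WT replicate 2 and Hetero KO replicate 3 stood apart here, with mean levels of 1.16 and 1.34 log2 CPM in the late 2-cell list against 1.80 to 2.41 in the other 6 libraries, and 4.12 and 4.03 in the other list against 3.46 to 3.79. Cumulus and blood markers had medians of 1.69 and 1.12 in Homo KO against WT, calls that were lost with an estimated correlation and, as given above, without single libraries.

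Without WT replicate 2, the medians in Homo KO against WT were 0.33 and -0.19, and without WT replicate 1 the first was 1.08. Without Homo KO replicate 3 the first was 0.33. In Hetero KO against WT the calls were lost without WT replicate 2 (0.088 and -0.0057), and the medians were 0.81 and -0.33 without WT replicate 1 and 0.46 and -0.33 without Hetero KO replicate 3. The first was 0.11 without Hetero KO replicate 1, and the other -0.10 without Hetero KO replicate 2. In Homo KO against Hetero KO, the median of the late 2-cell list turned to -0.012 without Hetero KO replicate 3 and to -0.025 without Homo KO replicate 3. It was 0.38 without Hetero KO replicate 1, 0.23 without Hetero KO replicate 2 and 0.26 without Homo KO replicate 1. The median of the other list was -0.034 without Hetero KO replicate 3, where its call was lost, and -0.26 without Hetero KO replicate 2 and without Homo KO replicate 1. In the morula knockdown, lists defined between the late 2-cell and 4-cell stages had medians of -0.10 and 0.03 and did not pass (camera adjusted p = 0.0701). With 286 genes at their bounds the first was -0.15.

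Across genes, which are not independent replicates, log2 fold changes of the morula knockdown and of Homo KO against WT, which share no library, had a Pearson r of -0.204 and a Spearman rho of -0.295 over 6568 genes. Of these genes 39.7% had the same sign. At an unadjusted p under 0.05, 11 genes were higher in both, against 5.6 for independent lists, and 0 were lower in both, against 10.9. For the late 2-cell knockdown and Homo KO against WT, r was -0.131, rho was -0.129 and 46.4% of genes had the same sign. For the knockdown at the late 2-cell stage and at the morula, r was 0.069, rho was 0.070 and 51.7% of 7787 genes had the same sign. Hetero KO and Homo KO against the same WT libraries had an r of 0.633 and a rho of 0.630, with 74.4% of 6965 genes of the same sign. Unchanged groups simulated against those WT libraries gave a mean r of 0.603, at most 0.664, and 70.5% of the same sign. The covariance was 0.1789 against 0.1198 in the simulations, a difference of 0.0591 and above their highest value of 0.1503. At an unadjusted p under 0.05, 131 genes were higher in both and 114 lower in both. The 2 WT libraries are too few to be split, so how much of this overlap comes from the shared controls is not known. These were 4 relations in 1 family, given without tests.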

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

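Results are given here because the knockdown effect differed between the stages, by the camera test of the difference itself over the 4 knockdown groups with a preset correlation. With an estimated correlation the adjusted p = 0.674 for each of the 3 lists. As given for the stage comparison of the controls, neither setting decides alone whether a list changed. The difference, morula minus late 2-cell, had a median of -0.51 on the log2 scale in the 2-cell ZGA list, whose medians were 0.23 at the late 2-cell stage and -0.09 at the morula. It was -0.43 in the p53 target list, with 0.12 at the late 2-cell stage and -0.33 at the morula. It was -0.44 in the ribosomal protein list, with 0.35 at the late 2-cell stage and -0.08 at the morula. The call of the 2-cell ZGA list was lost without siControl late 2-cell replicate 1 (-0.54), siPcgf5 late 2-cell replicate 2 (-0.51) or siPcgf5 morula replicate 2 (-0.39), so it depends on single libraries. So does that of the p53 targets, lost without siControl late 2-cell replicate 1 (-0.33), siPcgf5 late 2-cell replicate 1 (-0.34) or replicate 2 (-0.37), siControl morula replicate 2 (-0.25) or siPcgf5 morula replicate 1 (-0.37). The ribosomal protein call was kept without each library in turn, at -0.18 without siControl late 2-cell replicate 1 and -0.70 without siControl late 2-cell replicate 2. The ZGA median was -0.93 without siControl late 2-cell replicate 2, -0.18 without siControl morula replicate 1 and -0.94 without siPcgf5 morula replicate 1. No group held enough libraries for an outlier test within the group.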

How the results depend on the processing

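The ribosomal protein list without its S6 kinases and Rps19bp1 was chosen after the data were seen, with medians of 0.37 at the late 2-cell stage, -0.09 at the morula, -0.45 for the difference, -0.39 in Homo KO against WT, -0.23 in Hetero KO against WT and -0.14 in Homo KO against Hetero KO, and every call of the list was kept. Of 1395 values of named genes with 1 library left out, 1301 stayed on their side of the threshold without a large move, 2 were weaker, 5 stronger and 87 moved. Of 720 values of fixed lists 525 stayed so, with 43 weaker, 34 stronger and 118 moved. Of 967 values of fixed lists under the other alternatives, 845 stayed so, with 45 weaker, 24 stronger and 53 moved. Of 1645 values of named genes under those, 1526 stayed so, with 2 weaker, 62 stronger and 55 moved. Among these, 0 values past the threshold changed sign, while values not past it could, such as Zscan4d and Usp17lc in Hetero KO against WT, at 0.77 and 2.90 without WT replicate 1. Where no cause is named, the cause was not tested. Depth limits low genes, since a gene at 0 in a group could stand at up to 3 counts over it.

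With DESeq2 size factors the late 2-cell knockdown had 2 genes higher and 3 lower, against 1 and 1, and the stage lists at the morula had medians of -0.053 and 0.075, past the threshold. With no filter on low counts, more genes were tested, and the counts were 15 higher and 14 lower for the late 2-cell knockdown, 7 and 23 for the morula, 13 and 21 for the difference, 39 and 21 for Homo KO against WT, 1 higher for Hetero KO against WT and 1 higher for Homo KO against Hetero KO. The stage difference of Pcgf5 in controls was then -1.43, no longer past the threshold, and the blood list there stood at -6.43. With the DESeq2 Wald test the counts were 27 and 45, 5 and 18, 18 and 14, 234 and 94, and, for Hetero KO against WT, 6 and 1, and for Homo KO against Hetero KO, 89 and 22. Pcgf5 passed at -2.99 in the late 2-cell knockdown, -2.48 in the morula and -0.71 in Homo KO against WT, and the stage lists at the morula stood at -0.051 and 0.075. With limma on log2(TPM + 1) the late 2-cell knockdown had 8 higher and 6 lower, the difference 1 lower, Homo KO against Hetero KO 2 higher, the stage comparison 2452 higher and 7388 lower, and the stage lists at the morula stood at -0.014 and 0.045. Lists that kept their call moved too, to 0.23 for ribosomal proteins in the late 2-cell knockdown, -0.25 for p53 targets and -0.26 for ribosomal proteins in the difference, and 1.00 and 0.76 for cumulus markers in Homo KO against WT and against Hetero KO. The cause was not tested.

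With only the groups compared, the late 2-cell knockdown had 0 genes lower, the morula 1 lower and Homo KO against Hetero KO 1 higher. Pcgf5 in the morula was -2.50 and passed, and the stage lists at the morula stood at -0.12 and 0.059. With genes beyond a log2 fold change of 1 these lists stood at -0.10 and 0.025, past the threshold with more genes. With an estimated correlation the stage lists no longer passed, at the same medians of 0.55 and -0.37 in Homo KO against WT, 0.30 and -0.18 in Hetero KO against WT, and 0.15 and -0.17 in Homo KO against Hetero KO. The cause was not tested.

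With the replicate block, the late 2-cell knockdown had 0 genes higher and Pcgf5 passed at -2.85. The p53 target list for the difference (-0.41) and the chromatin repressors (-0.16) and ribosomal proteins (-0.10) in Homo KO against Hetero KO no longer passed, and the pluripotency list in Homo KO against WT stood at -0.57 and the 2-cell ZGA list there at 1.29. The block ended no other list call. Whether the replicate numbers pair the samples is not stated. Same-numbered libraries had correlations of their deviations, across genes, of -0.085 at the late 2-cell stage, 0.036 at the morula and -0.292 to 0.388 at the 4-cell stage. These values have no reference and cannot decide it.

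With 1 library left out, which leaves fewer samples, the late 2-cell knockdown had 0 to 5 genes higher and 0 to 8 lower, and Pcgf5 from -3.45 to -2.14. The morula had 0 to 4 lower, the difference 0 to 1 lower, Homo KO against WT 0 to 26 higher, and Homo KO against Hetero KO 0 to 3 higher and 0 to 1 lower. The stage difference of Pcgf5 in controls ran from -1.98 to -0.67. Stage lists ran from -0.25 to 0 and -0.0063 to 0.078 at the morula, and from 0.088 to 0.81 and -0.33 to -0.0057 in Hetero KO against WT. In Homo KO against Hetero KO they ran from -0.025 to 0.38 and -0.26 to -0.034. The late 2-cell list turned negative there without Hetero KO replicate 3 (-0.012) and without Homo KO replicate 3 (-0.025).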

Other observations

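Obox genes, a homeobox family of oocytes and early embryos, stood apart in 2 of the 8 4-cell libraries, of different genotypes. Their mean level was 8.14 on the log2 CPM scale in Hetero KO replicate 1 and 8.54 in Homo KO replicate 3, against 5.05 to 6.56 in the other 6 libraries. Obox2 stood at 484 and 734 CPM in these libraries and at 13.6 to 44.7 CPM in the others. Obox1 stood at 299 and 303 CPM, Obox5 at 541 and 438 CPM and Obox7 at 77.1 and 78.1 CPM. Obox6 did not follow, at 1800 to 2769 CPM over the 8 libraries. These genes were named after their values were seen.

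Of the tests below, those of the spread between libraries, of the splits with DESeq2, of the second stage matching, of Xist and of the widened ranges were chosen after the results were seen. The 2-cell ZGA list was higher in Homo KO than in Hetero KO, with a median of 0.94. The tables argue against a single library as the cause, since the lowest median with 1 library left out was 1.01. The ZGA list lay at percentile 100 of 10000 random lists matched on expression and on the stage difference. The same held with matching on the late 2-cell to 4-cell difference. Random lists of the first matching had a median of 0.09, all but 5% of them from -0.12 to 0.30. Members of the ZGA list move together, and with that range widened by their estimated correlation of 0.27, to -0.62 to 0.80, the median still lay above it. Camera with this estimated correlation did not pass for the list, with an adjusted p = 0.437. With an estimated correlation camera did not pass for the stage difference of this list either, so this cannot decide. These matched lists cannot decide about developmental timing of the pools. The WT pools share a genotype but differed widely in the ZGA list, and WT replicate 2, the lower, also stood apart in the stage lists. Developmental timing and the spread between libraries of 1 genotype stay open. The difference was 1.74 of its standard errors with the spread taken over all 3 genotypes, and 3.78 with the spread of the 6 libraries compared, since the WT pair differs most. Which of these spreads applies is not known. Loss of the repeat and of Pcgf5 mRNA, and the higher cumulus and blood markers of the same libraries, stay open and untested.

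The ribosomal protein list was lower in Homo KO than in WT, with a median of -0.38. It lay at percentile 0 of matched random lists (median -0.12, all but 5% of them from -0.21 to -0.0087), but this does not exclude developmental timing. The random lists hold unrelated genes, while the members have an estimated correlation of 0.64, and with the range widened by it, to -0.81 to 0.77, the median lay inside. The spread between libraries of 1 genotype could account for it, as the difference in mean log2 CPM was -1.4 of its standard errors, or -1.35 with the spread of the 5 libraries compared. The genotype stays open and untested.

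Xlr4a and Xlr4c, X-linked genes, had higher values in all 3 Homo KO libraries than in both WT libraries, and so had all 3 Hetero KO libraries. Fewer male embryos in the Homo KO pools could account for this, and the summed CPM of 8 Y-linked genes would then be lower in Homo KO, but it was 1.41 times that of WT. It ran from 106 to 264 CPM in Homo KO and from 118 to 152 CPM in WT, so the libraries overlap. Xist, expressed in female embryos, would be higher in Homo KO with fewer males, but stood at 40.5, 6.11 and 5.64 CPM there against 11.7 and 64.2 CPM in WT. Both go against fewer males, but with this overlap the sex makeup of the pools stays open. It also stays open, untested, for X-linked genes lower in Homo KO than in Hetero KO, such as Atrx, Kdm6a and Nxf2. Xlr4a stood at 70.7 and 90.0 CPM in siControl late 2-cell libraries and at 8.95 and 23.2 CPM in siControl morula libraries. For Xlr4c these values were 101 and 97.4 CPM and 28.55 and 52.3 CPM. Developmental timing of the pools therefore stays open and untested for Xlr4a and Xlr4c too. The genotype stays open and untested.

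For Homo KO against Hetero KO, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. With edgeR the real split gave 0 genes and the highest other 1, and since every split gives at least 0, that count says nothing about chance. With DESeq2 the real split gave 111 genes and the highest other 132, and 2 of 10 splits gave as many.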
